A study of Mus musculus with 18 samples.

How the data were processed

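Total RNA was sequenced from cultured peritoneal macrophages of 6-week-old C57BL/6 mice. Per the labels' protocols, each mouse received 1 mL of 3% thioglycollate, an irritant that draws macrophages into the peritoneal cavity, 3 days before the cells were collected. The cells attached to plates for 4 h and were then given 20 µM PCN (pregnenolone 16α-carbonitrile, a ligand of the mouse nuclear receptor PXR) or its solvent DMSO for 12 h. RNA was taken with TRIzol and libraries were made with Illumina protocols. Per the labels, 1 genotype (FF) carried floxed alleles of PXR, and the other (dMye) lacked PXR in myeloid cells. The 18 libraries fell into 4 groups: FF_DMSO and FF_PCN with 3 libraries each, and dMye_DMSO and dMye_PCN with 6 each. Replicate numbers in the text only name libraries. The labels do not say whether libraries of a group came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical.

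The values the authors deposited are expected counts per gene, that is estimated read counts that need not be whole. Reads were set against genome build mm10, per the submitters' processing notes. The aligner, the quantifier, the gene annotation and any use of strand are not given in the sources used here. The table named 21831 genes by symbol. Of these, 3171 were at 0 in all libraries and 26 carried date-like symbols of the kind a spreadsheet makes from gene names, which were kept as they stood and are not named here. Genes with near-identical copies, such as Lyz1 and Lyz2, Oas1a, Hspa8 or the MHC class II genes, share reads that expected counts divide by estimate, so their values are less certain than those of single-copy genes, and overlapping or antisense genes could not be told apart. Coordinates were taken from the GENCODE M21 annotation of GRCm38, matched by symbol for all 114 genes named in the text and for 98.7% of the tested genes.

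Expected counts were rounded to whole numbers. Library totals ran from 21993687 to 30228032. A count of 3, used as the floor where a gene had 0 counts, corresponds to between 0.0992 and 0.136 CPM (counts scaled to the library total), and such floors and intervals cover counting error only. Genes were kept by filterByExpr, which left 13409. One edgeR quasi-likelihood fit (edgeR 4.0.16, R 4.3.3, robust, TMM scaling) held all 18 libraries and 4 groups, without covariates. Its 5 contrasts were PCN against DMSO in FF, PCN against DMSO in dMye, the difference between these effects (dMye minus FF, the interaction), and dMye against FF under DMSO and under PCN. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. Log2 fold changes come from that fit, and their standard error (SE) is the size of the fold change divided by the square root of its F statistic. The biological coefficient of variation was 9.7%. Group levels are mean ± SD in CPM of unscaled library totals unless called TMM-scaled, with n = 3 in each FF group and 6 in each dMye group. A list score is the mean log2 CPM of a list's tested members, compared by two-sided exact permutation tests over libraries and adjusted over the lists. For the difference between the PCN effects, PCN and DMSO labels were shuffled within each genotype. That test assumes no PCN effect in either genotype, so real PCN effects make it harder to pass. With 3 libraries against 3 the smallest p such a test can give is 0.1, and with 6 against 6 it is 0.0022.

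The design, the tests, the alternatives, 32 gene lists and the rule for named genes were fixed before the data were examined. The lists covered xenobiotic and lipid metabolism, inflammatory and stress responses, energy metabolism, proliferation, antigen presentation, and markers of macrophages and of other cells of the peritoneal cavity, including mesothelial cells and fibroblasts. The 31 lists with at least 3 tested members were tested with camera (limma 3.58.1), which compares a list's genes with all others, at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry stand beside it. The count of changed members is given over all genes tested and adjusted over the list alone. Of the listed genes, Mx2, Clec7a, Ighm, Ighd, Igkc, Trac and Xist were not analysed here. The rule named, for each contrast, the largest rises and falls among called genes that reached 1 CPM in a compared group and whose libraries did not overlap (not required for the interaction), then up to 4 called members of each list by smallest p. Gene models, Xist and the listed Y-linked genes were left out of the largest changes. Other genes of the X chromosome were kept, among them Fgf16, P2ry10 and Kctd12b. Nr1i2 (the PXR gene), Lyz2, Cd36, Cyp3a11, Cyp3a13, Abcb1a, Abcb1b, Abca1, Abcg1, Il1b and Tnf were always included. Some genes that the rule selects are not reported here.

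Alternatives were RLE and upper-quartile scaling, no filter and a stricter filter (1 CPM in 6 libraries), DESeq2 1.42.0, limma-voom without and with quality weights, a fit of only the groups compared, edgeR without robust dispersion, 3 of 6 estimated surrogate variables (sva 3.50.0), a test against a 1.2-fold change (glmTreat), removal of 128 mitochondrial, ribosomal protein and haemoglobin genes, each library left out in turn, and random subsets of 3 dMye libraries. For the subsets, 40 were drawn for PCN against DMSO in dMye and all 20 were used for each genotype contrast. Fits without dMye_DMSO libraries 5 and 6, and fits with the mesothelial and fibroblast score as a covariate, were added after seeing the data.

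The tests were checked on simulated counts drawn from the means and library sizes of the tested genes. With 100 genes changed 1.5-fold and 100 changed 2-fold, edgeR recovered 66% and 87% in the simulation of PCN against DMSO in FF (13182 genes), 82% and 96% in that of dMye (13165 genes), and 57% and 81% in that of the interaction (13182 genes). For dMye against FF it recovered 74% and 92% under DMSO and 75% and 94% under PCN (13157 genes each). Contrasts given with the same number of genes were read from the same simulated counts. In the simulated interaction the changed genes responded to PCN in FF alone, so its recovery does not describe effects present in both genotypes. Between 5 and 11 unchanged genes were called per contrast. Camera called the changed list in each of the 5 contrasts and 0 of 30 unchanged lists in each. The simulated genes were drawn independently, so this does not check list calls where genes are correlated. In the data the estimated correlation was as high as 0.74, for oxidative phosphorylation genes with PCN in FF. Figures were drawn with matplotlib 3.10.9.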

Results

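The transcriptome of thioglycollate-elicited peritoneal macrophages was measured in 18 libraries. Macrophages with floxed PXR alleles (FF) or with PXR deleted in myeloid cells (dMye) received the PXR ligand PCN or DMSO for 12 h. The groups were FF_DMSO (n = 3), FF_PCN (n = 3), dMye_DMSO (n = 6) and dMye_PCN (n = 6). Totals ran from 24213247 to 27502208 expected counts in the FF libraries and from 21993687 to 30228032 in the dMye libraries. At this depth 1 CPM stands for 22 to 30.2 counts. Between 15075 and 15909 genes had a count in each library. No pair of replicates agreed within sampling noise, with a chi-square per gene between 3.98 and 51.5, so no pair was merged as a repeat of 1 library, which does not show that the libraries are independent. The first principal component held 42% of the variance and separated the genotypes, with every FF library between -52.1 and -40.7 and every dMye library between 18.5 and 28.3. On the next 2 components dMye_DMSO 5 and dMye_DMSO 6 lay at opposite ends of their group, at 22.8 and -14.3 and at -8.7 and 23.9. By chi-square per gene, dMye_DMSO 6 was near dMye_DMSO 1 and 3 (7.1 and 7.2). Library dMye_DMSO 4 was further from these (17.45 and 18.72). The FF_PCN libraries also spread on these components, from -31.2 to -4.6 and from -26.5 to 7.2.

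The targeted gene could not serve as a check of the genotype labels. Nr1i2 (GRCm38 chromosome 16, 38248323 to 38294824, minus strand), which encodes PXR, had 3 counts over the 6 FF libraries and 5 over the 12 dMye libraries, with at most 3 in any library, and did not pass the filter. Expression of PXR and its loss were therefore not detectable at this depth. Lyz2, the locus that drives Cre in many myeloid deletion lines, stood at 7140 ± 324 CPM in FF_DMSO and 4060 ± 646 in dMye_DMSO (log2 fold change -0.84, SE 0.11, adjusted p = 1.5e-05), but the labels do not name the Cre line. The Y-linked gene Ddx3y was at 46.2 ± 3.66 CPM in FF_DMSO and 57.9 ± 4.45 in FF_PCN, and at 0.0166 ± 0.0406 and 0.228 ± 0.211 in dMye_DMSO and dMye_PCN. It exceeded 1 CPM in 6 of 6 FF libraries and in 0 of 12 dMye libraries, and all 4 sex-linked genes tested were lower in dMye under both treatments (camera adjusted p = 1.9e-125 and 2.2e-113). Sex therefore followed genotype in all 18 libraries, and every contrast between FF and dMye is also a contrast between sexes.

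PCN changed lipid and inflammatory genes in FF macrophages. Idi1, an enzyme of cholesterol synthesis, fell from 9.68 ± 0.768 to 5.26 ± 0.597 CPM, Stard4, a sterol carrier, fell from 5.26 ± 0.422 to 2.22 ± 0.5, and Angptl4, an inhibitor of lipoprotein lipase, fell from 9.85 ± 1.24 to 1.78 ± 1.30 (n = 3 per group). Inhba, which encodes a subunit of activin, rose from 24.5 ± 1.5 to 61.7 ± 7.4 CPM, and Abcg1, a cholesterol exporter, rose from 397 ± 19.1 to 580 ± 35.9. For each of these genes all 3 PCN libraries lay beyond all 3 DMSO libraries. Of the 13409 genes tested, 1851 changed, 915 upwards and 936 downwards, and 25 of the rises and 93 of the falls reached 2-fold.

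Among the largest rises, log2 fold changes were 1.58 (SE 0.36, adjusted p = 0.0044) for Zdhhc2, 1.54 (SE 0.47, adjusted p = 0.032) for Wnk2, 1.52 (SE 0.25, adjusted p = 0.00018) for the phosphatase gene Dusp8, 1.36 (SE 0.12, adjusted p = 1.5e-07) for Inhba (chromosome 13, 16011851 to 16031621) and 1.16 (SE 0.18, adjusted p = 0.00011) for the small GTPase gene Gem. Among the largest falls were those of Angptl4 (chromosome 17, 33773750 to 33781830) at -2.45 (SE 0.33, adjusted p = 3e-05), the nucleotide receptor gene P2ry6 at -2.10 (SE 0.22, adjusted p = 1.4e-06), Gamt at -2.06 (SE 0.43, adjusted p = 0.0021) and Cmbl at -1.93 (SE 0.50, adjusted p = 0.011). The libraries of both groups did not overlap for these 9 genes, as the naming rule required, which 10% of unchanged genes would meet by chance with 3 libraries against 3.

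**Figure D1:**
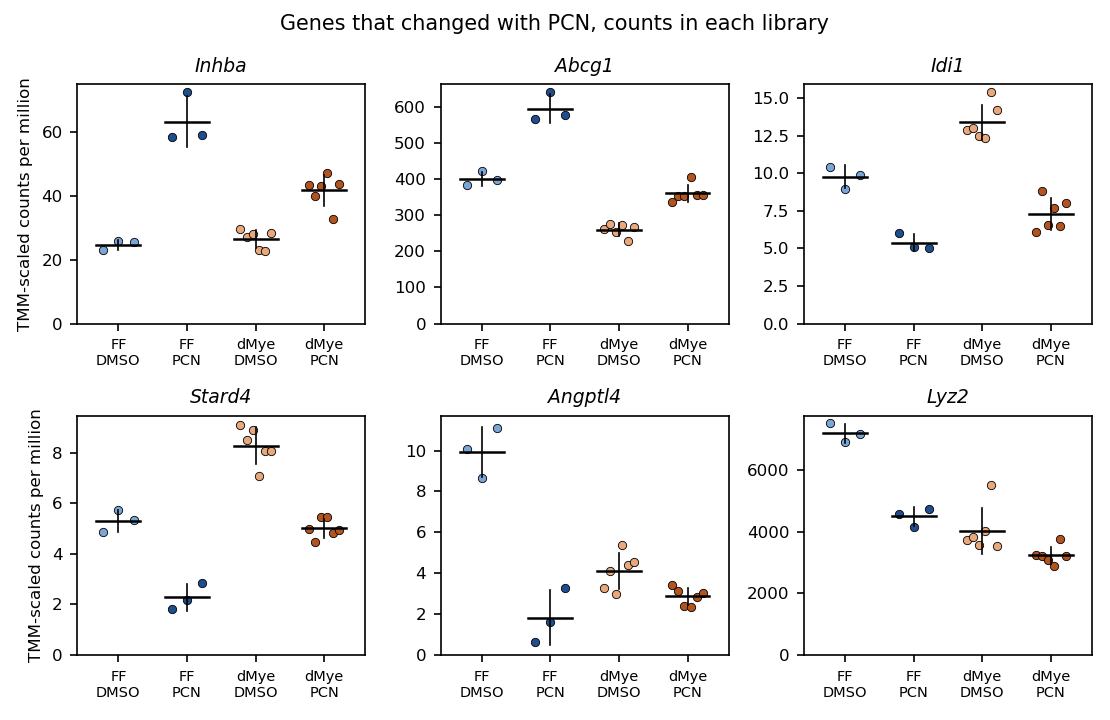
TMM-scaled CPM of Inhba, Abcg1, Idi1, Stard4, Angptl4 and Lyz2 in each library of the 4 groups, where points are libraries, bars are group means and lines span ± 1 SD. Idi1 fell to 0.553 of its DMSO level in FF and to 0.544 in dMye, while Angptl4 fell to 0.183 in FF.

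Lipid genes of FF macrophages moved in both directions. Of 25 tested genes of cholesterol synthesis and its SREBP2 programme, 8 fell and 1 rose (the same adjusted over the list alone). The list fell against other genes (camera adjusted p = 1.2e-05). Stard4 fell to 0.428 and Idi1 to 0.553 of their DMSO levels. Of 19 cholesterol efflux and LXR target genes, 5 rose and 3 fell (5 and 5 adjusted over the list alone), with no shift of the list (median log2 -0.05, camera direction up, adjusted p = 0.75). Abcg1 rose 1.49-fold, Abca1 1.42-fold, the ubiquitin ligase gene Mylip 1.6-fold and Arl4c 1.39-fold. The list of PPAR targets and fatty acid oxidation genes fell, with 7 of 19 members lower and 2 higher (9 and 3 adjusted over the list alone, camera adjusted p = 0.0012, but adjusted p = 0.079 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, fell from 223 ± 3.85 to 136 ± 0.939 CPM. In the list of lipoprotein uptake and lipid storage, 6 of 23 members fell and 2 rose (7 and 3 adjusted over the list alone). Its camera adjusted p was 0.046 (adjusted p = 0.075 with an estimated correlation), and the lysosomal lipase gene Lipa fell from 1570 ± 24.8 to 1080 ± 20.5 CPM and Scarb1 from 44.6 ± 0.441 to 32.4 ± 1.65. The scavenger receptor gene Cd36 stood at 2880 ± 41.3 and 2980 ± 96.5 CPM (log2 0.07, SE 0.07, adjusted p = 0.53). Fatty acid synthesis genes showed no shift as a list, with 2 of 15 lower and 0 higher by either adjustment (median log2 -0.13, camera adjusted p = 0.21).

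Of 36 drug metabolism and transport genes known as PXR targets in liver and gut, 15 were tested, of which 3 fell and 1 rose (4 and 1 adjusted over the list alone, camera direction down, adjusted p = 0.048, but adjusted p = 0.19 with an estimated correlation). The drug exporter genes Abcb1b and Abcc3 fell to 0.747 and 0.677 of their DMSO levels and Gstm1 to 0.863. Por, the electron donor of cytochrome P450 enzymes, rose from 623 ± 13.2 to 766 ± 21.0 CPM. Abcb1a was at 11.2 ± 1.84 and 9.47 ± 1.11 CPM (adjusted p = 0.38). Cyp3a11, a PXR target of liver, had 0 counts in all 6 FF libraries, which allows at most 0.124 CPM per library, and Cyp3a13 had 5 counts in FF_DMSO and 9 in FF_PCN.

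Inflammatory mediators rose in FF macrophages given PCN. Of 25 tested NF-kB driven genes, 10 rose and 1 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.00064). The cytokine gene Il1a rose from 39.8 ± 2.20 to 64.4 ± 5.19 CPM, the chemokine gene Ccl3 from 56.3 ± 2.16 to 91.4 ± 0.652, Ptgs2, which encodes cyclooxygenase 2, from 3.30 ± 0.213 to 5.48 ± 0.673, the inhibitor gene Tnfaip3 1.27-fold and Tnf 1.31-fold (adjusted p = 0.0067). Il1b had at most 18 counts in any FF library and was not tested. Genes induced by glucocorticoids rose as a list, with 6 of 19 higher and 2 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.00068). Among them the phosphatase gene Dusp1 rose from 70.1 ± 1.16 to 110 ± 5.10 CPM and Tgm2 rose 1.30-fold. Of 24 genes of the unfolded protein and integrated stress responses, 5 rose and 6 fell (7 and 7 adjusted over the list alone, camera adjusted p = 0.065). Ppp1r15a rose from 183 ± 5.08 to 327 ± 16.4 CPM and Atf3 1.43-fold. Interferon-stimulated genes fell as a list, with 5 of 27 lower and 0 higher (7 and 0 adjusted over the list alone, camera adjusted p = 0.0012). Oas2 fell to 0.431 and Oasl2 to 0.578 of their DMSO levels.

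Genes of antigen presentation, macrophage identity and proliferation fell in FF macrophages given PCN. Of 14 MHC class II presentation genes, 6 fell and 0 rose (10 and 0 adjusted over the list alone, camera adjusted p = 2e-06). Cd74 was at 234 ± 10 and 162 ± 15.7 CPM, H2-Eb1 at 49.9 ± 4.50 and 32.8 ± 4.99, and Ifi30 at 164 ± 12.2 and 112 ± 6.09. B cell markers, whose cells also carry MHC class II, moved with them, with 4 of 12 lower and 0 higher (8 and 0 adjusted over the list alone, median log2 -0.88, camera adjusted p = 0.00064). Cd79a and Bank1 fell to 0.545 and 0.458 of their DMSO levels. Of 18 macrophage markers, 8 fell and 0 rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.00017). Lyz2 fell from 7140 ± 324 to 4390 ± 317 CPM, the receptor gene Csf1r to 0.763, Mertk to 0.692 and Timp2 to 0.743 of their levels. Monocyte markers fell in 3 of 10 (5 adjusted over the list alone, camera adjusted p = 0.001). F13a1 was at 40.7 ± 2.99 and 27.3 ± 0.665 CPM. Proliferation genes fell in 5 of 30 by either adjustment (camera adjusted p = 0.0036). Mki67 was at 9.69 ± 0.536 and 6.23 ± 0.300 CPM and Cdc20 at 0.571 of its DMSO level. Neutrophil markers did not shift as a list (median log2 -0.28, mean 0.14, camera adjusted p = 0.15). Of its genes 2 of 9 fell, among them Mmp8 to 0.617. The share of mitochondrial transcripts was between 1.81% and 2.02% in FF_DMSO and between 1.46% and 1.72% in FF_PCN. Of 13 mitochondrially encoded genes 3 fell (4 adjusted over the list alone, camera adjusted p = 0.00055, but adjusted p = 0.29 with an estimated correlation). mt-Co3 was at 0.679 of its DMSO level. Mesothelial and fibroblast markers fell in 1 of 16 (camera adjusted p = 0.0089, but adjusted p = 0.23 with an estimated correlation).

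With an estimated correlation, 9 of the 16 lists called in FF kept an adjusted p under 0.05, namely sterol synthesis, glucocorticoid, NF-kB, interferon, proliferation, MHC class II, macrophage, monocyte and B cell. The number of changed genes was 315 in a test against a 1.2-fold change and 1201 without FF_DMSO 1, and upper-quartile scaling lowered the share of rises from 49.4% to 38.2%. The list calls of xenobiotic and of lipid uptake genes, and the gene calls of Abca1, Bank1, Cd79a, Cmbl, Oas2 and Wnk2, were lost without 1 or another library among FF_DMSO 1, FF_DMSO 3 and the 3 FF_PCN libraries (highest gene adjusted p between 0.058 for Cmbl and 0.13 for Bank1 and Wnk2), the lipid uptake and mesothelial calls also without FF_DMSO 2 (adjusted p = 0.069 and 0.064), the mesothelial call without FF_PCN 1 (adjusted p = 0.093), and that of Cdc20 in limma-voom (adjusted p = 0.077). Without FF_PCN 3 the log2 fold change was -3.17 for Angptl4 and -2.81 for Cmbl.

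In dMye macrophages PCN also lowered genes of cholesterol synthesis. Idi1 fell from 13.5 ± 1.07 to 7.34 ± 1.05 CPM, Stard4 from 8.35 ± 0.818 to 5.06 ± 0.377 and Fdps from 19.7 ± 2.16 to 12.2 ± 1.55 (n = 6 per group). Abcg1 rose from 263 ± 22.1 to 364 ± 22 CPM and Inhba from 26.8 ± 3.45 to 42.1 ± 5.10. For each of these genes all 6 PCN libraries lay beyond all 6 DMSO libraries. Of the 13409 genes, 279 changed, 126 upwards and 153 downwards, and 0 of the rises and 4 of the falls reached 2-fold.

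The largest rises were those of Inhba (log2 0.65, SE 0.08, adjusted p = 0.00018), Abcg1 (0.47, SE 0.05, adjusted p = 2.3e-05), the ephrin receptor gene Epha2 (0.42, SE 0.10, adjusted p = 0.022), Mylip (0.40, SE 0.05, adjusted p = 0.00011), the oxysterol-binding gene Osbp2 (0.38, SE 0.09, adjusted p = 0.023) and Il1a (0.37, SE 0.06, adjusted p = 0.0026). Among the largest falls were those of Gpr162 (-1.75, SE 0.35, adjusted p = 0.011), Idi1 (-0.88, SE 0.09, adjusted p = 2.3e-05), Timd4, a phosphatidylserine receptor of resident macrophages (-0.81, SE 0.21, adjusted p = 0.04), and Kctd12b (-0.81, SE 0.10, adjusted p = 9.7e-05).

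The sterol synthesis list fell with 11 of 25 members lower and 0 higher (16 and 0 adjusted over the list alone, camera adjusted p = 2e-34, and adjusted p = 1.2e-06 with an estimated correlation). Cyp51 fell to 0.722 and Stard4 to 0.605 of their DMSO levels. The mean of the list in log2 CPM moved by -0.378 (SE 0.026) in dMye, the smallest p an exact permutation test allows here (p = 0.0022, adjusted p = 0.018), and by -0.357 (SE 0.045) in FF (exact permutation p = 0.1, again the smallest possible). The effects differed by -0.021 (SE 0.052, exact permutation p = 0.94). This permutation assumes no PCN effect in either genotype, so its p cannot show that the effects are equal. Of 19 efflux and LXR target genes 4 rose and 1 fell (5 and 1 adjusted over the list alone, median log2 -0.08, camera direction up, adjusted p = 0.75). Arl4c was up 1.14-fold. Abca1 was at 52.6 ± 8.61 and 63.5 ± 8.84 CPM (adjusted p = 0.17). The PPAR and fatty acid oxidation list fell (2 of 19 lower and 0 higher, 4 and 1 adjusted over the list alone, camera adjusted p = 0.0027, but adjusted p = 0.11 with an estimated correlation). Cpt1a was at 0.767 of its DMSO level. Fatty acid synthesis genes fell in 1 of 15 (2 adjusted over the list alone, camera adjusted p = 0.031, but adjusted p = 0.11 with an estimated correlation). In lipid uptake, 2 of 23 fell (3 and 1 rise adjusted over the list alone, camera adjusted p = 0.055), namely Lipa to 0.865 and Scarb1 to 0.828, and Cd36 was at 2230 ± 128 and 2270 ± 118 CPM (adjusted p = 0.87). Of the 15 xenobiotic genes 0 changed (1 rise and 1 fall adjusted over the list alone, camera adjusted p = 0.18). Abcb1b was at 43.1 ± 3.19 and 41.7 ± 2.43 CPM (adjusted p = 0.73), Abcb1a at 12.6 ± 1.47 and 11.1 ± 1.51 (adjusted p = 0.41) and Cyp3a11 at 1 count over all 12 libraries.

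NF-kB driven genes rose in 5 of 25 with 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 0.00028, and adjusted p = 0.0046 with an estimated correlation), among them Ptgs2 1.27-fold, Tnfaip3 1.16-fold and the chemokine gene Ccl7 1.31-fold. Tnf was at 13 ± 0.182 and 14.6 ± 1.24 CPM (adjusted p = 0.22). Glucocorticoid-induced genes rose in 1 of 19, namely Dusp1 1.14-fold (2 rises and 1 fall adjusted over the list alone, camera adjusted p = 0.026, but adjusted p = 0.10 with an estimated correlation). Of the stress response genes 4 of 24 rose and 0 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.28). Ppp1r15a was up 1.27-fold and Atf3 1.15-fold. The interferon list fell without any single gene passing the test in edgeR by either adjustment (camera adjusted p = 0.0027, and adjusted p = 0.038 with an estimated correlation). Macrophage markers fell in 2 of 18, namely Timp2 to 0.862 and Csf1r to 0.880 (4 adjusted over the list alone, camera adjusted p = 0.002, and adjusted p = 0.038 with an estimated correlation). Lyz2 was at 4060 ± 646 and 3270 ± 278 CPM (adjusted p = 0.086). Of the MHC class II genes 1 of 14 fell, Ifi30 to 0.842 (1 fall and 1 rise adjusted over the list alone, camera adjusted p = 0.056), and B cell markers moved in 0 of 12 (median log2 0.02, camera adjusted p = 0.56). Other lists that fell with 0 genes called were proliferation (camera adjusted p = 0.018), monocyte (adjusted p = 0.04), mesothelial and fibroblast (3 lower adjusted over the list alone, adjusted p = 0.018), mitochondrially encoded (2 lower adjusted over the list alone, adjusted p = 0.0021) and oxidative phosphorylation genes (adjusted p = 0.01). With an estimated correlation these had adjusted p = 0.09, 0.15, 0.33, 0.42 and 0.69. Of the lists called by camera in dMye, the fatty acid synthesis, macrophage, monocyte, glucocorticoid, mitochondrially encoded and oxidative phosphorylation scores did not pass the exact permutation test (adjusted p = 0.052, 0.053, 0.055, 0.23, 0.3 and 0.66).

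The count of 279 was 584 in DESeq2, 466 with quality weights, 144 in a fit of only the dMye groups, 8 in a test against a 1.2-fold change and 179 without dMye_DMSO libraries 5 and 6, and without a single library it was 166 (dMye_DMSO 2), 137 (dMye_PCN 3), 144 (dMye_PCN 4) or 167 (dMye_PCN 6), while upper-quartile scaling moved the share of rises from 45.2% to 31.2% and removal of abundant RNA classes to 57.7%. Each of the 12 libraries except dMye_DMSO 5 and dMye_DMSO 6, left out alone, ended the call of at least 1 of Arl4c, Ccl7, Epha2, Osbp2 and Timd4, whose highest adjusted p over the alternatives was between 0.068 and 0.13, and the list calls of fatty acid synthesis, glucocorticoid, proliferation, monocyte and mesothelial genes were also lost without single libraries.

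**Figure D2:**
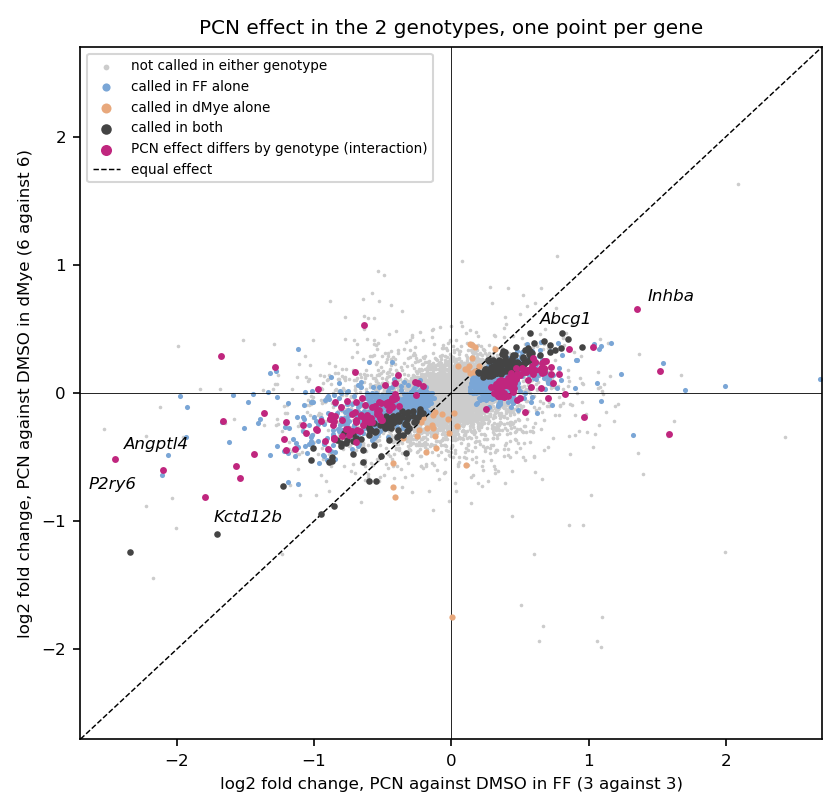
Log2 fold change of PCN against DMSO in FF (horizontal axis) and in dMye (vertical axis) for 11720 genes that reached 1 CPM in a group mean, with genes coloured by the test they passed and 15 genes lying outside the axes. Over genes above 8 CPM the slope of the dMye change on the FF change was 0.32, and 0.43 after correction for noise in the FF change.

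Whether the effect of PCN depended on genotype was tested by the interaction. The rises of Ppp1r15a, Dusp1 and Ccl3 were smaller in dMye than in FF, by log2 -0.52 (SE 0.07, adjusted p = 0.00044), -0.48 (SE 0.07, adjusted p = 0.0014) and -0.52 (SE 0.09, adjusted p = 0.0038). The falls of P2ry6, Lipa and the chaperone gene Hspa8 were smaller too, by 1.49 (SE 0.26, adjusted p = 0.0062), 0.30 (SE 0.06, adjusted p = 0.011) and 0.40 (SE 0.07, adjusted p = 0.0056). The interaction passed the test for 190 genes, 100 with a more positive and 90 with a more negative effect in dMye. For all 190 the effect was larger in size in FF. The same effects enter the interaction, so this is no separate support for a smaller effect in dMye. Of the 190 genes, 189 were called in FF and 51 in dMye, and 28 had opposite signs.

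Other genes with a more positive effect in dMye were Slit2, Mrgprf at 2.86 (SE 0.68, adjusted p = 0.037), Cenpk at 1.97 (SE 0.47, adjusted p = 0.037) and Angptl4 at 1.93 (SE 0.40, adjusted p = 0.02). More negative effects were those on Evc2 at -2.92 (SE 0.63, adjusted p = 0.023), Zdhhc2 at -1.91 (SE 0.42, adjusted p = 0.025), Dusp8 at -1.35 (SE 0.30, adjusted p = 0.024), Rin1 at -1.16 (SE 0.23, adjusted p = 0.015) and Pcnx at -0.84 (SE 0.17, adjusted p = 0.021). The value for Evc2 ran from -6.74 without FF_DMSO 2, where the other FF_DMSO libraries are at 0 and the fit depends on the prior count, to -2.33 without FF_DMSO 3 (adjusted p = 0.086). Without FF_PCN 3 the value was 3.82 for Mrgprf and 2.66 for Angptl4. Slit2 had 0 counts in FF_PCN and 0.386 ± 0.229 CPM in FF_DMSO, at least 3.22-fold higher against a floor of 3 counts per library, and 1.48 ± 0.418 and 2.41 ± 0.677 CPM in dMye_DMSO and dMye_PCN. Among list members the effect also differed for Abcb1b (0.37, SE 0.09, adjusted p = 0.044), Cpt1a (0.31, SE 0.07, adjusted p = 0.03), Cd74 (0.44, SE 0.08, adjusted p = 0.011), F13a1 (0.45, SE 0.11, adjusted p = 0.047) and Mmp8 (0.48, SE 0.12, adjusted p = 0.047). It differed in the other direction for Tgm2 (-0.29, SE 0.06, adjusted p = 0.021), Sgk1 (-0.26, SE 0.06, adjusted p = 0.039), Atf3 (-0.32, SE 0.07, adjusted p = 0.023), Gabarapl1 (-0.32, SE 0.07, adjusted p = 0.02) and the retinoid receptor gene Rxrb (-0.31, SE 0.07, adjusted p = 0.026).

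The effect on sterol synthesis genes did not pass the test of a difference (0 of 25 called, 1 lower adjusted over the list alone, camera adjusted p = 0.28), and Abcg1 differed by -0.10 (SE 0.09, adjusted p = 0.70) and Abca1 by -0.24 (SE 0.17, adjusted p = 0.61). Lyz2 (0.36, SE 0.16, adjusted p = 0.34), Cd36 (-0.05, SE 0.08, adjusted p = 0.87), Abcb1a (0.03, SE 0.18, adjusted p = 0.97) and Tnf (-0.22, SE 0.11, adjusted p = 0.43) did not pass either. The MHC class II list had a more positive effect in dMye (1 of 14, 5 adjusted over the list alone, camera adjusted p = 5.1e-06, but adjusted p = 0.092 with an estimated correlation). So had the B cell markers beside it (0 of 12, 4 adjusted over the list alone, median log2 0.94, camera adjusted p = 5.1e-06, and adjusted p = 0.0066 with an estimated correlation). Macrophage and monocyte markers were also more positive (0 of 18 and 1 of 10, 5 and 1 adjusted over the list alone, camera adjusted p = 0.016 for both, but adjusted p = 0.10 for both with an estimated correlation). The glucocorticoid list was more negative (3 of 19, with 5 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.016, but adjusted p = 0.092 with an estimated correlation). So were the NF-kB list (1 of 25 by either adjustment, adjusted p = 0.038, but adjusted p = 0.10 with an estimated correlation) and the lysosome list (1 of 26, 4 adjusted over the list alone, adjusted p = 0.017, but adjusted p = 0.43 with an estimated correlation). Proliferation, interferon, mesothelial and mitochondrially encoded lists were more positive with 0 genes called (camera adjusted p = 0.032, 0.048, 0.038 and 0.032), and had adjusted p = 0.10, 0.14, 0.37 and 0.49 with an estimated correlation. In the exact permutation test of list scores, no list passed for the difference between the effects (lowest adjusted p = 0.4). That test assumes no PCN effect in either genotype, so a list that does not pass may still differ. The B cell score differed by 0.916 (SE 0.163, exact permutation p = 0.016, adjusted p = 0.4) and the MHC class II score by 0.466 (SE 0.132, exact permutation p = 0.079, adjusted p = 0.53).

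Of the 279 genes called in dMye, 242 were called in the same direction in FF, where independent lists would share 8.6 rises and 10.7 falls against 113 and 129 observed, and 0 genes were called in opposite directions. Across 8704 genes, which are not independent replicates, the effects in both genotypes had a Pearson correlation of 0.59 and a Spearman correlation of 0.59, and these contrasts share no library. The interaction count was 426 in DESeq2, 439 with quality weights, 364 with surrogate variables and 8 in a test against a 1.2-fold change, and without a single library it was 42 (FF_DMSO 1), 104 (FF_DMSO 2), 50 (FF_DMSO 3), 105 (FF_PCN 1), 62 (FF_PCN 2), 93 (FF_PCN 3), 121 (dMye_DMSO 2), 122 (dMye_PCN 1) or 125 (dMye_PCN 2). Of the genes named above, Slit2, P2ry6, Lipa, Dusp1, Ccl3, Ppp1r15a and Hspa8 passed without any 1 library, whereas each other call was lost without at least FF_DMSO 1 (highest adjusted p between 0.063 for Cd74 and Rin1 and 0.15 for F13a1), and only the B cell, MHC class II, macrophage, monocyte and glucocorticoid list calls passed in every such fit. The share of more positive effects, 52.6%, was 60.3% with upper-quartile scaling, 64.9% without abundant RNA classes and 67.3% without a filter.

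The genotypes also differed without PCN. Under DMSO, dMye libraries had more transcripts of mesothelial cells and fibroblasts than FF libraries, with the keratin gene Krt19 at 25.8 ± 2.44 against 2.32 ± 0.496 CPM, the collagen gene Col3a1 at 239 ± 22.5 against 59.7 ± 3.25, Sparc at 138 ± 6.45 against 33.8 ± 3.42 and the proteoglycan gene Dcn at 105 ± 6.37 against 27.1 ± 0.665 (n = 6 and 3). Proliferation genes were higher too, with Top2a at 19.6 ± 2.39 against 6.68 ± 1.06 CPM, and B cell genes were lower, such as Cd79a at 1.83 ± 0.465 against 5.93 ± 0.650. Of the 13409 genes, 2921 differed, 1869 higher and 1052 lower in dMye, and 1030 and 72 of these by at least 2-fold. All dMye libraries lay above all FF libraries for Krt19, Col3a1 and Top2a.

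**Figure D3:**
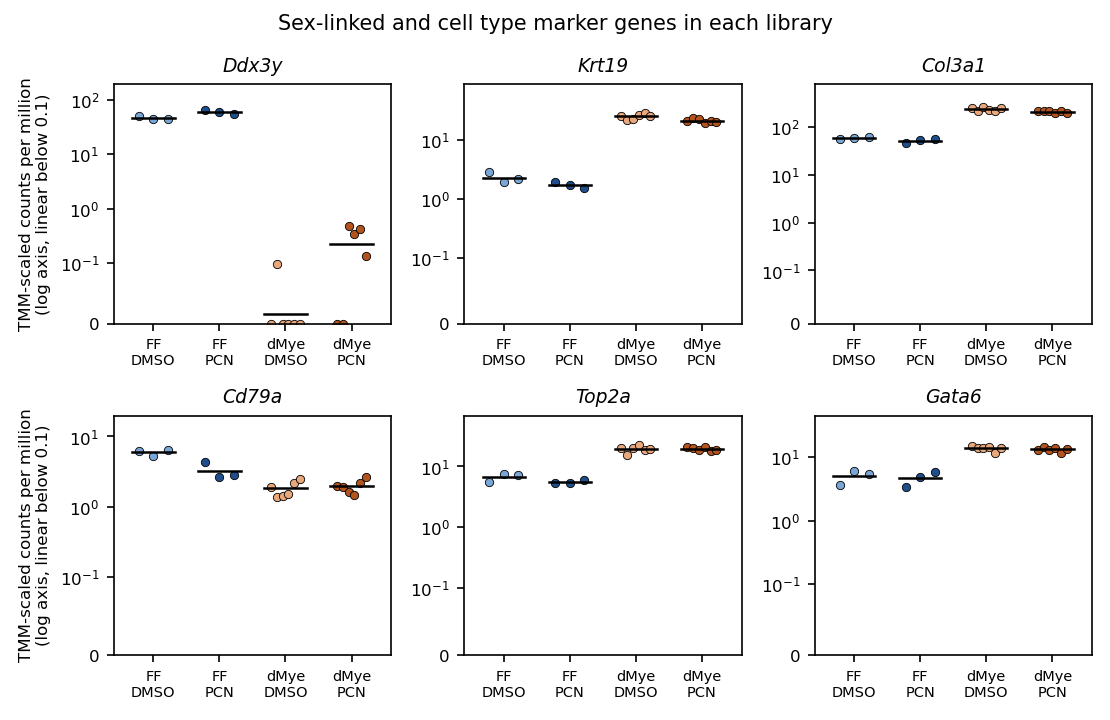
TMM-scaled CPM of Ddx3y, Krt19, Col3a1, Cd79a, Top2a and Gata6 in each of the 18 libraries on a log axis that is linear below 0.1, with bars at group means. Krt19 was 11-fold and Col3a1 3.94-fold higher in dMye than in FF under DMSO, and Ddx3y exceeded 1 CPM in 6 FF libraries and 0 dMye libraries.

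Among the genes most raised in dMye under DMSO, the ephrin receptor gene Ephb3 had 0 counts in FF_DMSO against 1.33 ± 0.492 CPM. This is at least 11.7-fold higher against a floor of 3 counts per library. The growth factor gene Fgf16 had 2 counts against 178, a ratio of CPM of 44.8 (95% counting interval 12.2 to 372). Evc2, Spon2 and Hoxc8 had log2 fold changes of 4.76 (SE 0.48, adjusted p = 1.1e-07), 4.63 (SE 0.51, adjusted p = 3.8e-07) and 4.47 (SE 0.60, adjusted p = 6.6e-06). These folds rest on few counts, since Evc2 and Spon2 were at 0 in 2 of the 3 FF_DMSO libraries and Hoxc8 in 1. Over the alternatives Evc2 had log2 values between 4.17 and 8.58 (without FF_DMSO 2), Spon2 between 4.02 and 9.27 (without FF_DMSO 1) and Hoxc8 between 3.88 and 5.43 (without FF_DMSO 1). The values of 8.58 and 9.27 stand against FF_DMSO libraries all at 0, so they depend on the prior count and are no bound. Among the largest falls were those of the B cell genes Pax5 (-2.37, SE 0.43, adjusted p = 0.00024), Ly6d (-2.32, SE 0.41, adjusted p = 0.00019), Fcmr (-2.14, SE 0.35, adjusted p = 7.8e-05), Ms4a1 (-2.06, SE 0.31, adjusted p = 2.5e-05) and Mzb1 (-2.01, SE 0.34, adjusted p = 1e-04). The lymphoid genes Lef1 and P2ry10 were at 0.213 and 0.224 of FF. Wdfy1 (chromosome 1, 79702262 to 79776143) was at 19.0 ± 2.86 against 73.5 ± 1.63 CPM.

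All 16 mesothelial and fibroblast markers were higher in dMye by either adjustment, with a median log2 of 2.18 (camera adjusted p = 7.9e-94). Of 30 proliferation genes 25 were higher and 0 lower by either adjustment (median log2 1.17, camera adjusted p = 1.9e-20). Ccnb2 was 4.65-fold higher. Markers of resident peritoneal macrophages were higher in 10 of 15 and lower in 2 by either adjustment (camera adjusted p = 4e-05). The transcription factor gene Gata6 was at 14.0 ± 1.29 against 5.02 ± 1.23 CPM, Timd4 at 2.77 ± 0.501 against 0.255 ± 0.132 and Prg4 2.23-fold higher. Under either treatment, which cells carried these transcripts was not tested, and mesothelial markers were higher in the same libraries. General macrophage markers did not shift as a list, with 8 of 18 higher and 2 lower by either adjustment (median log2 0.08, camera adjusted p = 0.083). Lyz1 was 2.96-fold and Timp2 1.25-fold higher, whereas Lyz2 stood at 0.560 of the FF level. B cell markers were lower in 9 of 12 (11 adjusted over the list alone, median log2 -1.66, camera adjusted p = 2.2e-08), and T and NK cell markers in 8 of 12 by either adjustment (camera adjusted p = 0.00092). Ccl5, which also stands in the NF-kB list, was at 0.627 and Il7r at 0.822 of FF. In the DMSO libraries Il7r was between 743.4 and 999.2 TMM-scaled CPM, above the macrophage marker Csf1r at 127.9 to 136.4. Which cells carried Ccl5 and Il7r was not tested. MHC class II genes, which B cells share, were lower in 9 of 14 by either adjustment (camera adjusted p = 5.3e-07). Cd74 was at 141 ± 7.59 against 234 ± 10 CPM and H2-Eb1 at 0.571 of FF. Neutrophil markers were lower in 3 of 9 by either adjustment (camera adjusted p = 0.012). Mmp8 was at 0.390 of FF.

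Sterol synthesis genes were higher in dMye under DMSO in 15 of 25 and lower in 0 by either adjustment (camera adjusted p = 0.00092). Insig1 was 1.41-fold higher. Fatty acid synthesis genes were higher in 6 of 15 and lower in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0031). The desaturase genes Scd1 and Scd2 were 2.23-fold and 3.38-fold higher. PPAR targets and fatty acid oxidation genes were lower in 7 of 19 and higher in 1 by either adjustment (camera adjusted p = 0.00028). The lipid droplet gene Plin2 was at 2290 ± 106 against 3360 ± 54.1 CPM, Cd36 at 2230 ± 128 against 2880 ± 41.3 and Cpt1a at 0.676 of FF. Lipid uptake genes were higher in 4 of 23 and lower in 8 (4 and 9 adjusted over the list alone, camera adjusted p = 0.21). The scavenger receptor gene Marco was 2.88-fold higher. Efflux and LXR target genes were higher in 6 of 19 and lower in 4 (6 and 5 adjusted over the list alone, camera adjusted p = 0.83). The transfer protein gene Pltp was 1.79-fold higher, Abcg1 at 0.650 of FF and Abca1 at 0.803 (adjusted p = 0.061). NF-kB driven genes were higher in 13 of 25 and lower in 2 (16 and 3 adjusted over the list alone, camera adjusted p = 0.00032). Ptgs2 was at 21.1 ± 2.19 against 3.30 ± 0.213 CPM and Vcam1 2.30-fold higher, while Tnf was 1.14-fold higher (adjusted p = 0.11). The xenobiotic list had 3 of 15 higher and 3 lower (4 and 3 adjusted over the list alone, median log2 0.14, camera direction down, adjusted p = 0.83). Cyp3a13 was at 0.548 ± 0.200 against 0.0608 ± 0.0556 CPM, Abcb1a 1.10-fold (adjusted p = 0.44) and Abcb1b 1.07-fold higher (adjusted p = 0.31). Chil3 was 1.79-fold and Hspb1 3.29-fold higher, and Fos at 0.594 of FF. With an estimated correlation all 12 list calls passed, with adjusted p between 1.4e-10 and 0.039. In a test against a 1.2-fold change 1338 genes differed, and upper-quartile scaling moved the share of higher genes from 64.0% to 76.0%.

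**Figure D4:**
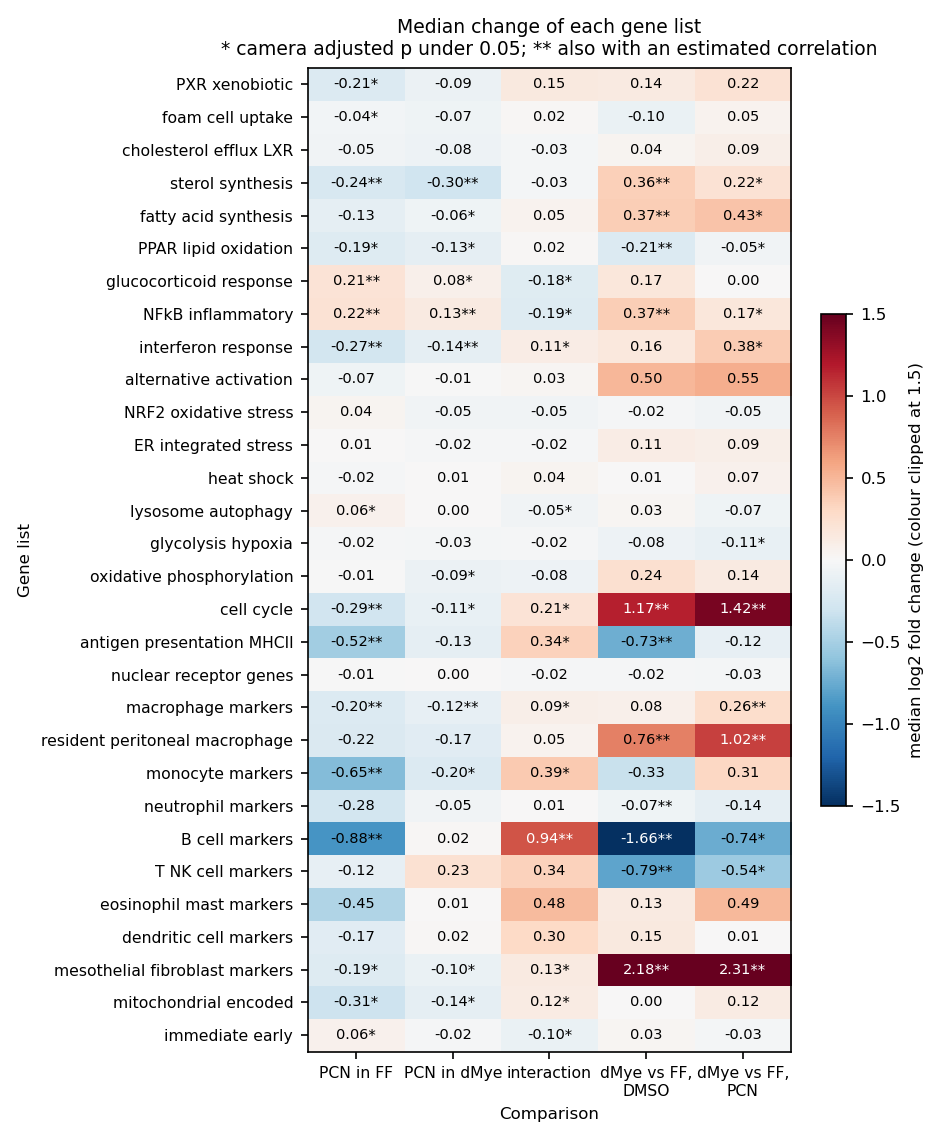
Median log2 fold change of the tested members of each gene list (rows) in the 5 contrasts (columns), with colours clipped at 1.5 and stars marking lists that passed camera (1 star) or also passed with an estimated correlation (2 stars). The mesothelial and fibroblast markers had medians of 2.18 and 2.31 in dMye against FF, and the sterol synthesis genes medians of -0.24 and -0.30 with PCN in FF and dMye.

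Mesothelial, fibroblast and proliferation genes also separated the genotypes under PCN. Krt19 stood at 21.9 ± 1.6 CPM in dMye against 1.70 ± 0.190 in FF, Col3a1 at 214 ± 10.6 against 50.7 ± 4.04, Top2a at 19.9 ± 1.25 against 5.45 ± 0.399 and Ptgs2 at 26.6 ± 2.25 against 5.48 ± 0.673 (n = 6 and 3). Por was lower in dMye, at 593 ± 23.0 against 766 ± 21.0 CPM, as were Abcg1, at 364 ± 22 against 580 ± 35.9, and Wdfy1, at 20.7 ± 2.25 against 80.8 ± 2.67. Of the 13409 genes, 3702 differed, 2176 higher and 1526 lower, and 1092 and 65 of these by at least 2-fold.

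Slit2 had 372 counts in dMye_PCN and 0 in FF_PCN, at least 20.1-fold higher against a floor of 3 counts per library. Arhgef28 and Igsf9 had 228 and 206 counts against 2 each, ratios of CPM of 55.7 (95% counting interval 15.3 to 463) and 50.4 (13.8 to 419). The FF_PCN counts lay in FF_PCN 1 alone for Arhgef28 and in FF_PCN 2 alone for Igsf9. Greb1 and Thbs2 had log2 fold changes of 5.23 (SE 0.57, adjusted p = 2.7e-07) and 4.98 (SE 0.31, adjusted p = 3.2e-11), which were 6.44 for Greb1 without FF_PCN 1 and 5.86 for Thbs2 without FF_PCN 2. Among the largest falls were those of Wdfy1 (-2.01, SE 0.09, adjusted p = 1e-13) and Gpr162 (-1.97, SE 0.40, adjusted p = 0.00078).

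Mesothelial and fibroblast markers were higher in 15 of 16 by either adjustment (camera adjusted p = 2e-90). Sparc was 4.21-fold higher. Proliferation genes were higher in 26 of 30 (27 adjusted over the list alone, camera adjusted p = 6e-23). Ube2c was 4.92-fold higher. Resident macrophage markers were higher in 12 of 15 with 1 lower by either adjustment (camera adjusted p = 1.3e-05). Gata6 was 2.81-fold and F5 2.03-fold higher. General macrophage markers were higher in 13 of 18 and lower in 1 (13 and 2 adjusted over the list alone, camera adjusted p = 0.0012). Lyz1 was 2.79-fold and Timp2 1.45-fold higher and Lyz2 at 0.720 of FF. B cell markers were lower in 4 of 12 (6 adjusted over the list alone, camera adjusted p = 0.043, but adjusted p = 0.12 with an estimated correlation). Fcmr was at 0.396 of FF. T and NK cell markers were lower in 5 of 12 and higher in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.031, but adjusted p = 0.057 with an estimated correlation). Il7r was at 0.770 of FF, and which cells carried it was not tested here either. MHC class II genes were lower in 5 of 14 and higher in 2 (6 and 2 adjusted over the list alone, camera adjusted p = 0.12). Ciita was at 0.452 and Cd74 at 0.8 of FF, and neutrophil markers lower in 1 of 9 by either adjustment, Mmp8 at 0.544 (camera adjusted p = 0.12).

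Sterol synthesis genes were higher in 10 of 25 and lower in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 0.043, but adjusted p = 0.14 with an estimated correlation). Stard4 was 2.20-fold higher. Fatty acid synthesis genes were higher in 6 of 15 and lower in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0076, but adjusted p = 0.05 with an estimated correlation). Scd2 was 3.63-fold and Scd1 2.77-fold higher. The PPAR list was lower in 7 of 19 and higher in 1 by either adjustment (camera adjusted p = 0.043, but adjusted p = 0.26 with an estimated correlation). Plin2 was at 0.679 and Cd36 at 0.735 of FF, and lipid uptake genes were higher in 4 of 23 and lower in 6 by either adjustment (camera adjusted p = 0.62). Efflux and LXR genes were higher in 7 of 19 and lower in 7 (8 and 7 adjusted over the list alone, camera adjusted p = 0.99). Pltp was 1.85-fold higher and Abca1 at 0.681 of FF. NF-kB driven genes were higher in 11 of 25 and lower in 3 (11 and 5 adjusted over the list alone, camera adjusted p = 0.043, but adjusted p = 0.064 with an estimated correlation). Vcam1 was 2.71-fold higher and Tnf at 14.6 ± 1.24 against 14.5 ± 1.00 CPM (log2 -0.04, SE 0.08, adjusted p = 0.77). Interferon-stimulated genes were higher in 11 of 27 and lower in 0 (14 and 0 adjusted over the list alone, camera adjusted p = 0.043, but adjusted p = 0.12 with an estimated correlation). Gbp2 was 1.69-fold and Oas1a 1.43-fold higher. Of the xenobiotic list 4 of 15 were higher and 2 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.50). Cyp3a13 was at 0.738 ± 0.252 against 0.118 ± 0.102 CPM, Abcb1b 1.39-fold and Abcb1a 1.13-fold higher (adjusted p = 0.33). Dusp1 was at 0.670, Chil3 1.83-fold, Hspb1 3.42-fold and Hspa8 1.34-fold relative to FF.

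In the genotype contrasts, which share no library, 1405 genes were higher and 531 lower under both treatments, where independent lists would share 303.3 and 119.7, and 26 were called in opposite directions. In a test against a 1.2-fold change 1517 genes differed under PCN, and upper-quartile scaling moved the share of higher genes from 58.8% to 74.8%. Without dMye_PCN 4 the sterol, PPAR, NF-kB, interferon, glycolysis and B cell list calls were lost (adjusted p up to 0.064), as were some of these without FF_PCN 1 or FF_PCN 3 (adjusted p up to 0.13), the T and NK cell call without FF_PCN 3 (adjusted p = 0.067), and the calls of Fcmr without FF_PCN 1 and of Arhgef28 in limma-voom (highest adjusted p = 0.12 for both).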

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

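The tests with the B cell markers, Ddx3y, the macrophage markers and Nr1i2 were chosen after the results they measure were seen. The test with a second list of mesothelial and fibroblast genes, the subsets, the slopes, the count near Nr1i2 and Lyz2 and the splits were chosen before. Each pattern was found and tested on the same data, so the explanations are hypotheses.

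Mesothelial and fibroblast genes were higher in dMye under both treatments. A candidate source is a larger share of such cells in the dMye cultures, and a second list of 19 tested markers written before the test was higher too, with a median log2 of 1.51 under DMSO (14 higher, 0 lower, range 0.02 to 3.23). The most abundant of its genes, Fbln2 and Fstl1, stood at 104 and 105 CPM in dMye_DMSO against 30 and 46.7 in FF_DMSO, none of the genes of either list stands in another list, and which of them macrophages also express was not tested. A lower share of macrophages that raised every other cell type alike is argued against by the B cell markers, which had a median log2 of -1.66. Sex cannot be told apart from this, since Ddx3y exceeded 1 CPM in 0 dMye libraries and in 6 of 6 FF libraries, and attachment to plates for 4 h is the only selection of cells the labels give.

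The response to PCN was smaller in dMye, with 279 genes against 1851 and a corrected slope of 0.43. Dilution of macrophage RNA by other cells was weighed with the macrophage markers. A log2 of about -1.22 would be needed if the other cells expressed each gene as macrophages do, without responding to PCN. The median of the markers was 0.08 under DMSO (range -0.84 to 1.56), so they were not lower as a set. How far other cells express each gene was not tested, so the markers cannot decide on dilution. The number of libraries is argued against by the design, since each dMye group had 6 libraries and each FF group 3. Subsets of 3 against 3 dMye libraries gave at most 309 genes (median 21, 40 subsets). Fewer libraries tend to lower a count in any case, so the subsets add no support. If noise in the FF changes made the slope small, the corrected slope would lie near 1. Over 18 leave-one-out fits it was at most 0.45 (without FF_DMSO 2) and at least 0.38 (without dMye_DMSO 5). Loss of PXR in myeloid cells cannot be told apart from other differences between the genotypes, because the highest Nr1i2 count in any library was 3. Sex of the animals also stays open, untested.

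Of the genes that differ between genotypes under both treatments, those near Nr1i2 and Lyz2 were counted. Within 10 Mb of Nr1i2 or Lyz2, 37 of 179 tested genes (20.7%) were called in both treatments, against 1878 of 13051 elsewhere (14.4%). The odds ratio was 1.55 (95% interval 1.05 to 2.25, Fisher exact p = 0.024, two-sided). The ratio met the criterion set beforehand for strain-derived sequence next to a targeted locus. That criterion was set aside, because the ratio does not test this explanation for the reasons below. Such sequence therefore cannot be told apart from other differences between the genotypes. The labels do not name the Cre line, so Lyz2 is not known to be targeted, and a floxed Nr1i2 allele with its flanks would be shared by both genotypes. Genes next to each other are also not independent.

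Other groupings of the same libraries were counted. For PCN against DMSO in FF, 1 of 10 splits, the real one, gave 1851 genes and the highest other gave 1, and 10 splits are too few for a share under 0.05. For PCN in dMye, 100 of 462 possible splits were drawn and 1, the real one, reached 279 (highest other 261). This share under 0.05 argues against a random grouping only if the libraries are independent, which the labels do not say. For the interaction, 10 of 100 drawn splits gave at least 190 genes (highest other 1381). All 10 kept the FF labels, which keeps the PCN effect in FF within the contrast, while the 90 that regrouped the FF libraries gave at most 1. The counts thus follow a structure of the samples, the PCN effect in FF, and the share of 10 in 100 decides nothing about chance. For dMye against FF, 1 of 84 splits reached 2921 under DMSO (highest other 1772) and 1 of 84 reached 3702 under PCN (highest other 1). These shares too argue against a random grouping only if the libraries are independent.

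In groups of 6 libraries, 18 of 236 tests placed 1 library far from the other 5 by Dixon's ratio, where chance gives about 1 in 20, or 11.8. Levels are TMM-scaled CPM with the range of the other 5 in brackets. Library dMye_DMSO 5 was apart for Ccl3 at 83.6 (68.7 to 73.8), Lyz2 at 5530 (3540 to 4040), Tnf at 13.8 (12.6 to 13), Lyz1 at 108 (73.3 to 84.5), Gata6 at 11.9 (13.9 to 14.8), Ccl5 at 6.73 (4.66 to 5.21) and the share of ribosomal protein transcripts at 4.65% (3.13 to 3.52). Library dMye_DMSO 1 was apart for Gamt at 2.06 (0.907 to 1.08), and dMye_DMSO 4 for Arl4c at 30.7 (34.2 to 36). Library dMye_DMSO 6 was apart for Abcc3 at 16.8 (13 to 14.4), Arhgef28 at 0 (1.04 to 1.58) and Igsf9 at 1.85 (0.94 to 1.26). Library dMye_PCN 2 was apart for Cd74 at 148 (125 to 132), and dMye_PCN 4 for Abcg1 at 407 (337 to 357) and Cenpk at 0.843 (1.04 to 1.15). Library dMye_PCN 5 was apart for mt-Co3 at 1690 (1400 to 1490), Chil3 at 323 (260 to 282) and Oas1a at 84.8 (72.6 to 76).

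For 25 named genes the effect of PCN differed between dMye and FF by a test of the interaction, given here as the difference in log2 with its SE. The difference was 7.04 (1.12) for Slit2, whose FF_PCN libraries are all at 0, so that the fitted value depends on the prior count and is no bound. It was 2.86 (0.68) for Mrgprf, 1.97 (0.47) for Cenpk, 1.93 (0.40) for Angptl4, 1.49 (0.26) for P2ry6, -2.92 (0.63) for Evc2 (-6.74 without FF_DMSO 2, where the other FF_DMSO libraries are at 0, so that this value is no bound either), -1.91 (0.42) for Zdhhc2, -1.35 (0.30) for Dusp8, -1.16 (0.23) for Rin1 and -0.84 (0.17) for Pcnx. Among metabolic genes it was 0.37 (0.09) for Abcb1b, 0.30 (0.06) for Lipa and 0.31 (0.07) for Cpt1a. Among signalling and stress genes it was -0.48 (0.07) for Dusp1, -0.29 (0.06) for Tgm2, -0.26 (0.06) for Sgk1, -0.52 (0.09) for Ccl3, -0.52 (0.07) for Ppp1r15a, -0.32 (0.07) for Atf3, 0.40 (0.07) for Hspa8, -0.32 (0.07) for Gabarapl1 and -0.31 (0.07) for Rxrb. Among marker genes it was 0.44 (0.08) for Cd74, 0.45 (0.11) for F13a1 and 0.48 (0.12) for Mmp8. Apart from Slit2, P2ry6, Lipa, Dusp1, Ccl3, Ppp1r15a and Hspa8, each of these calls was lost without FF_DMSO 1, with highest adjusted p between 0.063 and 0.15.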

How the results depend on the processing

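The fits without dMye_DMSO libraries 5 and 6 and those with the mesothelial and fibroblast score as a covariate were chosen after seeing the data. No paired analysis was possible because the labels give the groups no shared replicate number. Scaling moved the median change over all genes by at most 0.06 in log2.

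With PCN in FF, 1851 genes changed, 315 in a test against a 1.2-fold change, which asks for larger effects by construction, and between 1201 (without FF_DMSO 1) and 1437 (without FF_DMSO 2) in leave-one-out fits, which hold fewer samples. With PCN in dMye, 279 genes changed, 584 in DESeq2, 466 with quality weights, 144 in a fit of only these groups, 8 against a 1.2-fold change, 179 without dMye_DMSO libraries 5 and 6, a median of 21 with 3 libraries per group, and between 137 (without dMye_PCN 3) and 371 (without dMye_PCN 5) leaving out 1 library. The interaction had 190 genes, 426 in DESeq2, 439 with quality weights, 364 with surrogate variables, 8 against a 1.2-fold change, and between 42 (without FF_DMSO 1) and 261 (without dMye_DMSO 5) leaving out 1 library. DESeq2 called 16 unchanged simulated genes in the FF setting and 24 in that of the interaction, against 8 and 9 in edgeR. In that setting false calls were too few to account for 426 interaction genes against 190. The simulated genes were independent and had the spread that edgeR estimated, so this does not bound false calls in the data. PCN in dMye was not simulated with DESeq2, and the cause of these differences was not tested. For dMye against FF, a test against a 1.2-fold change gave 1338 genes under DMSO and 1517 under PCN, and each other alternative run gave a count within 1.5-fold of 2921 and 3702. With the mesothelial and fibroblast score as a covariate, 1585 genes were called in FF (1370 shared with the fit reported), 340 in dMye (241 shared) and 162 for the interaction (145 shared). Of the named calls 8 were lost there, Wnk2 in FF, Arl4c, Ccl7 and Timd4 in dMye, and Abcb1b, F13a1, Mrgprf and Sgk1 for the interaction (adjusted p between 0.053 for Mrgprf and 0.13 for Timd4).

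Camera with an estimated correlation called 9 of the 16 lists in FF, 4 of 12 in dMye, 1 of 12 for the interaction and 5 of 13 for dMye against FF under PCN. Fry, which asks a different question, called 22 lists under DMSO and 24 under PCN for dMye against FF. Leaving out 1 library gave between 6 (without FF_DMSO 2) and 13 (without FF_DMSO 1) lists for the interaction and between 7 (without dMye_PCN 4) and 17 (without FF_PCN 2) for dMye against FF under PCN, and the cause was not tested.

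Signs changed only for values near 0 that passed no test in the fit reported. Cd36 with PCN in dMye was 0.02, 0 with surrogate variables and between -0.01 and 0.05 leaving out 1 library. The interaction of Abcb1a was 0.03, -0.01 with surrogate variables and between -0.05 and 0.16 leaving out 1 library. For dMye against FF, Tnf under PCN was -0.04, 0.02 with upper-quartile scaling and between -0.1 and 0. The cause was not tested.

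Of the genes named as called, 31 of 51 in FF, 5 of 27 in dMye, 2 of 25 for the interaction, 44 of 46 under DMSO and 37 of 42 under PCN passed in every alternative, and the test against a 1.2-fold change alone ended 69 calls. At 22 to 30.2 counts per CPM, genes under 1 CPM such as Nr1i2, Cyp3a11 and Il1b lie at or near the limit of what these libraries count.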

Other observations

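The tests of lists were planned, and the ratio test of the sterol synthesis list was chosen after the result was seen. Lysosome and autophagy genes rose as a list with PCN in FF, with 8 of 26 higher and 0 lower (10 and 1 adjusted over the list alone, camera adjusted p = 0.022, but adjusted p = 0.45 with an estimated correlation). Gabarapl1 rose 1.30-fold. That list call was lost without FF_DMSO 3 (adjusted p = 0.054) and without FF_PCN 3 (adjusted p = 0.056), and the list did not shift in dMye (adjusted p = 0.75) or between genotypes under DMSO (adjusted p = 0.63) and PCN (adjusted p = 0.052). Immediate early genes rose with PCN in FF in 5 of 16 and fell in 2 (6 and 4 adjusted over the list alone, camera adjusted p = 0.043, but adjusted p = 0.17 with an estimated correlation), a call lost without FF_DMSO 2, FF_DMSO 3 or FF_PCN 1 (adjusted p up to 0.1). In dMye 3 rose and 1 fell (adjusted p = 0.75), and the difference between the effects was negative (adjusted p = 0.037, but adjusted p = 0.15 with an estimated correlation). Under DMSO 4 were higher and 2 lower in dMye (adjusted p = 0.58), and under PCN 3 and 7 (adjusted p = 0.062). Of 23 glycolysis and hypoxia genes, 4 rose and 2 fell in FF (adjusted p = 0.75), among them the glucose transporter gene Slc2a1 1.57-fold and Ndrg1 1.28-fold higher, and 2 rose and 2 fell in dMye (adjusted p = 0.75). Under PCN 7 were lower in dMye than in FF and 0 higher (8 and 0 adjusted over the list alone, camera adjusted p = 0.043, but adjusted p = 0.29 with an estimated correlation), with Hilpda at 0.583, and under DMSO 1 was lower (adjusted p = 0.063). Oxidative phosphorylation genes fell as a list with PCN in dMye with 0 of 28 called in edgeR (median log2 -0.09, camera adjusted p = 0.01, but adjusted p = 0.69 with an estimated correlation), a call lost without dMye_DMSO 5 (adjusted p = 0.72) and without dMye_PCN 4 (adjusted p = 0.1). In FF 1 fell (adjusted p = 0.75), and between genotypes adjusted p was 0.14 under DMSO and 0.43 under PCN.

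Alternative activation genes did not shift with PCN in FF (2 of 19 higher, 1 lower) or dMye (0 of 19), with adjusted p = 0.75 for both, and 10 of 19 were higher and 2 lower in dMye under DMSO (adjusted p = 0.083) and 9 higher and 3 lower under PCN (adjusted p = 0.069), neither of which passed. Of 20 oxidative stress genes 3 rose and 4 fell in FF (adjusted p = 0.97) and 1 rose and 1 fell in dMye (adjusted p = 0.24). Their list did not shift between genotypes under DMSO (adjusted p = 0.52) or PCN (adjusted p = 0.28). Of 24 stress response genes, 9 were higher and 3 lower in dMye under DMSO (adjusted p = 0.49), and 6 higher and 6 lower under PCN (adjusted p = 0.87). Heat shock genes had adjusted p = 0.14 in FF, 0.75 in dMye, 0.42 under DMSO and 0.069 under PCN. Of 21 nuclear receptor and coactivator genes 3 rose and 1 fell in FF (adjusted p = 0.72), 0 changed in dMye by edgeR (adjusted p = 0.75), and the list had adjusted p = 0.35 under DMSO and 0.24 under PCN. Resident macrophage markers with PCN had adjusted p = 0.099 in FF and 0.056 in dMye, T and NK cell markers 0.96 and 0.06, neutrophil markers 0.52 in dMye, and sex-linked genes 0.57 and 0.52. The resident macrophage score did pass the exact permutation test in dMye (-0.159, SE 0.042, exact permutation p = 0.0043, adjusted p = 0.028). Eosinophil and mast cell markers had adjusted p = 0.13 in FF, 0.96 in dMye, 0.86 under DMSO and 0.37 under PCN, and dendritic cell markers 0.32, 0.75, 0.82 and 0.28. The erythroid and platelet list had 2 tested members, too few for camera, and its score moved by 0.678 (SE 0.482, exact permutation p = 0.3) in FF and fell by 0.217 (SE 0.367, exact permutation p = 0.6) in dMye.

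The fall of sterol synthesis genes with PCN was present in both genotypes. If only myeloid cells contributed, an effect that needs myeloid PXR would have been near 0 in dMye. The mean of the list moved by -0.378 (SE 0.026) in dMye and by -0.357 (SE 0.045) in FF, a ratio of 1.06. The ratio cannot decide on a need for myeloid PXR. PXR in dMye libraries could not be checked from Nr1i2, and sex followed genotype. Mesothelial and fibroblast markers were higher in dMye, and which cells carried the sterol change was not tested. An effect of PCN on sterol synthesis that does not pass through PXR is a candidate explanation that was not tested.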
